A study of Homo sapiens with 46 samples.

How the data were processed

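The study measured 5-hydroxymethylcytosine (5hmC), an oxidised form of methylated cytosine, in formalin-fixed paraffin-embedded prostate tissue from human donors. Per the labels' protocols, 5hmC-carrying DNA was enriched by labelling and capture and amplified before sequencing, with 22 tumor and 24 adjacent normal libraries. No input library was analysed here, so a value reflects both the 5hmC of a gene and the number of DNA copies it has.

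Per the submitters' processing notes, the tools named were FastQC, fastp, MultiQC, Bowtie2, SAMtools, Picard, featureCounts of the Subread package and DESeq2, with the genome build hg38 (GRCh38). Their versions, and which part of a gene was counted, are not given in the sources used here. The authors deposited one table of normalized counts, a signal per gene and library that is not a raw count. Every value was a whole multiple of a library's own step (100% within 0.01), and the median-of-ratios size factor of the whole numbers times that step lay between 0.999 and 1.00 in the 46 libraries. The whole numbers served only to give depth, as counts per library in mega (M). Tumor libraries held a median of 10.7 M counts (range 2.99 to 34.3) and adjacent normal libraries a median of 13.04 M (range 4.54 to 25.9). They may not be raw reads, for a reason the closing section describes. The libraries fall into 2 sets by the form of their names, called name sets A and B here. Over all libraries the values of the 2 sets differed by less than those of random splits. The rows of the deposited table also lay nearly in the order of the p-values computed here (Spearman rank correlation across genes 0.966).

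The table held 20471 genes. Y-linked genes and X-inactivation RNAs (75) were left out, which left 20396 genes, and 17635 had a position in the RefSeq GRCh38.p14 table by symbol or by a synonym of 1 gene only. The lowest mean value was 37.1, so the minimum mean of 10 removed 0 genes. HOXB13, AMACR and GSTP1, which were among the genes fixed for description, were not analysed here.

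Tumor and adjacent normal libraries were compared with limma 3.58.1 in R 4.3.3 on log2(normalized count + 1), with a trended, robust empirical Bayes fit, two-sided, and Benjamini-Hochberg adjustment over all genes. The threshold was an adjusted p of 0.05. A log2 change is tumor minus adjacent normal on that scale. The added 1 shrinks the change of low genes, but libraries near 0 weigh heavily in a mean of logs. The change of a low gene can therefore be larger than its group means give. The 26 gene lists and the 41 chromosome arms with at least 5 measured genes were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation. The lists were androgen-responsive genes, markers of luminal, basal, and club and hillock epithelium, smooth muscle, fibroblasts, endothelium, T and NK cells, B and plasma cells, myeloid and mast cells, nerve and glia, and neuroendocrine cells, genes raised in prostate cancer RNA, genes with hypermethylated promoters in prostate cancer, cytosine methylation and demethylation enzymes, genes recurrently lost or mutated in prostate cancer, HOX genes, other developmental transcription factors, proliferation, homologous recombination and repair, the Wnt and TGF-beta pathways, PI3K and MAPK signalling, inflammation and interferon, hypoxia and glycolysis, and lipid and steroid metabolism. Only the genes of a list found in the deposited table, by symbol or synonym, could be tested, and the counts of a list are over these. They were fewest for HOX genes (6 of 39 fixed), developmental transcription factors (36 of 84), and inflammation and interferon genes (18 of 37). Because camera treats genes as nearly independent, each list and arm was also given 1 score per library, the median over its genes of the log2 value about the gene's mean, minus the same median over all genes, and the scores were compared by a two-sided permutation test (100000 resamples). That test was added after the data were seen. The spread of libraries was the mean distance of a library to its group's centroid over the 2000 most variable genes, compared by a permutation test.

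Genes named in the text were chosen by a rule set before the data were examined: the 12 genes with the smallest p in each direction, the 2 members of each list with the smallest p, and a set of genes named in advance. Some genes this rule picks are not reported here. The fit was tested on simulated data for tumor against adjacent normal, on 20396 genes. It recovered 44% of 50 genes changed 1.2-fold, 96% of 50 changed 1.5-fold and 100% of those changed 2-fold or 3-fold. It called 7 of 20196 unchanged genes and 0 of 25 unchanged lists. The simulated genes were drawn independently of each other, so the test says nothing of lists whose genes move together. Random splits of the real libraries called up to 14 lists, as the closing section describes.

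Names in the labels tie 5 donors to both tissues. The correlations across genes between the deviations of their tumor and normal libraries from the group means were mixed in sign, at -0.67, 0.46, 0.19, -0.22 and 0.14, which ranked 24, 2, 9, 20 and 7 among the 24 normals, genes not being independent. No 2 libraries of a group agreed within sampling noise, with a lowest chi-square per degree of freedom of 2.04 in tumors and 2.89 in normals. The alternatives planned before the data were examined were other pseudocounts, filters and scalings, a donor block, the name set as a covariate or on its own, libraries whose names hold an R left out, array weights, a depth covariate, a rank-sum test and the estimated correlation. Alternatives chosen after the data were seen were depth limits of 8 and 5 M counts, leaving out 1 normal library, and removal of trends over local gene density and gene length. Local gene density was the number of protein-coding genes in a window of 1 Mb centred on the gene. The trends were fitted and removed only over the 17635 genes with a position. Also chosen then were that removal in the deeper libraries, leaving out tumor 21 or each library in turn from the deeper libraries, and a library's spread about its gene length trend as a covariate. The limit of 8 M was picked after tumors that stood apart on the first principal component were seen to be mostly of low depth. GC content was not tested because no genome was used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.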

Results

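Levels of 5hmC over 20396 genes were compared between 22 prostate tumors and 24 adjacent normal tissues, all fixed and embedded in paraffin. Values are normalized counts, given as mean ± SD over the libraries of a group. Depth ranged from 2.99 to 34.3 M counts in tumors and from 4.54 to 25.9 M in adjacent normal tissue (M, mega), and 7 tumors and 4 normals had under 8 M. Log2 depth did not differ detectably between the groups (difference -0.07, permutation p = 0.767). Donors were told apart by the full names in the labels, by which 5 donors gave both tissues. Some numbers in the names recur between name sets A and B, and these were taken as different donors.

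The first comparison asked which genes carry more or less 5hmC in tumor. Higher 5hmC was found over MYO1D, an unconventional myosin, over GOLM1, which encodes a Golgi membrane protein, over ESRP1, a regulator of epithelial splicing, and over RAD54B and TPD52. Lower 5hmC was found over BLK, a tyrosine kinase of B cells, GNAO1, a G protein subunit, CYP1B1, a monooxygenase, SLC6A6, the taurine transporter, and HRH2, a histamine receptor. In all, 2334 genes were higher and 2573 lower by limma at an adjusted p under 0.05. Changes were small, with a median size of 0.28 on the log2 scale, and a fold of 1.5 or more was reached by 2 higher and 442 lower genes. In the 15 tumors and 20 normals with at least 8 M counts, a limit set after the data were seen, limma called 0 genes in either direction, with 4181 genes at an unadjusted p under 0.05 and a lowest adjusted p of 0.0884. That count depended on single libraries: among the deeper libraries 1082 genes were higher and 686 lower without tumor 12, 35 and 37 without tumor 11, and 1 and 0 without adjacent normal 7 or 14, while leaving out each of the other 31 gave 0. With at least 5 M counts, 1446 genes were higher and 1622 lower.

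MYO1D (chromosome 17, 32492522 to 32877124, GRCh38) had 2839 ± 275 normalized counts in tumor (SD, n = 22) and 2351 ± 167 in normal tissue (SD, n = 24). Its log2 change was 0.27 (SE 0.04, limma adjusted p = 0.000479), and 20 of 22 tumors lay above the normal median. GOLM1 (chromosome 9, 86026146 to 86100149) had 1023 ± 157 against 778 ± 112, a log2 change of 0.40 (SE 0.07, limma adjusted p = 0.00083), with 21 tumors above the normal median. EZH2, the histone methyltransferase (chromosome 7, 148807383 to 148884291), rose by 0.25 (SE 0.05, limma adjusted p = 0.000995), with 21 tumors above. BLK (chromosome 8, 11494387 to 11564599) had 402 ± 59.7 against 500 ± 40.9, a log2 change of -0.32 (SE 0.05, limma adjusted p = 0.00083), and only 1 tumor lay above the normal median. CYP1B1 (chromosome 2, 38067509 to 38076151) changed by -0.70 (SE 0.12, limma adjusted p = 0.00083), with 3 tumors above. The other genes with the smallest p were PGM2L1, ELOVL2-AS1, ENTREP2, ANOS1, DGAT2L6, GCNT1 and the row ENSG00000227463 among the higher genes, and LINC01937, MYBPHL, LINC02135, C4orf54, XKR5 and the rows ENSG00000261070 and ENSG00000266667 among the lower ones. The antisense gene ELOVL2-AS1 may share counts with overlapping genes. Log2 changes ran from 0.25 in ENTREP2 to 0.42 in DGAT2L6 and from -0.32 in BLK to -0.70 in CYP1B1. In the deeper libraries the adjusted p of these 24 genes lay between 0.0884 and 0.105, and all 24 had the same direction, which is not independent evidence, since they were picked on libraries that include these.

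**Figure D1:**
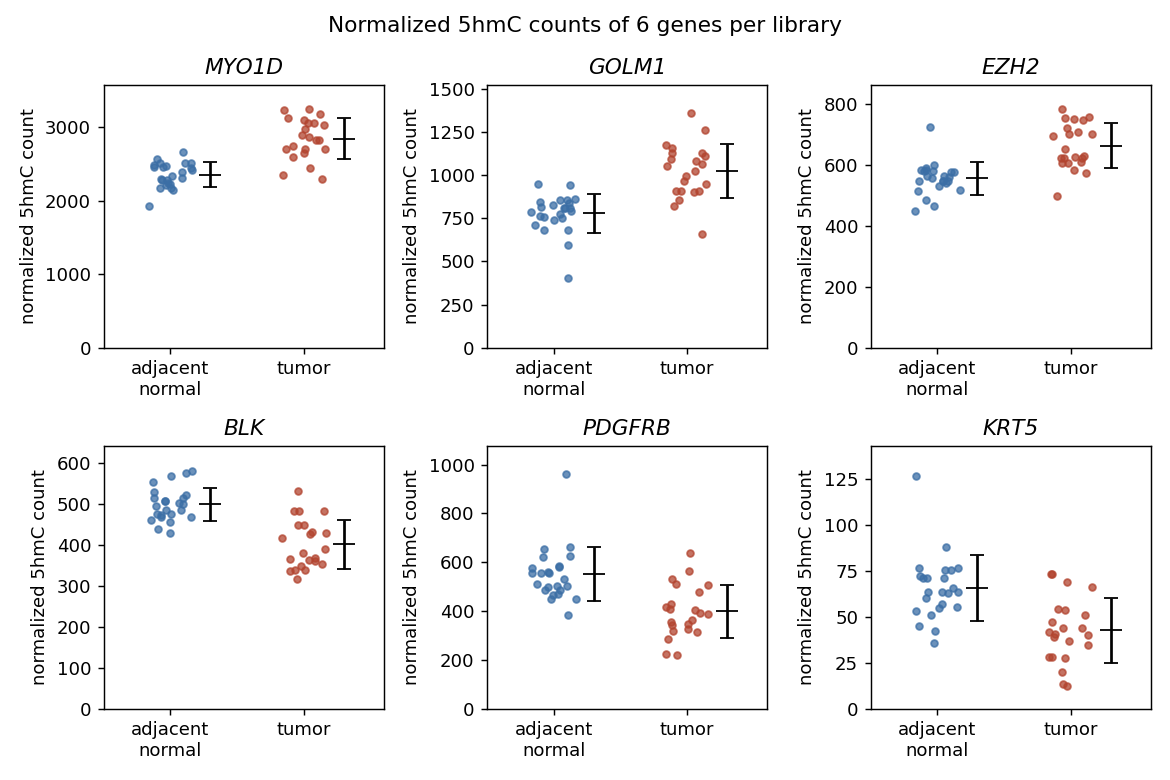
Normalized 5hmC counts (y axis, from 0) of MYO1D, GOLM1, EZH2, BLK, PDGFRB and KRT5 in each adjacent normal (blue, n = 24) and tumor (red, n = 22) library, with black bars for mean ± SD. MYO1D averaged 2839 in tumor and 2351 in normal tissue, BLK 402 and 500, and the groups overlap for each gene.

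Markers of the tissue's muscle, stroma and basal epithelium carried less 5hmC in tumor. Among 19 smooth muscle genes 6 were lower and 0 higher, with a median log2 change of -0.18 (camera adjusted p = 9.66e-05, and adjusted p = 0.286 with an estimated correlation). The lower ones included SMTN (-0.38) and SYNM (-0.59), which encode proteins of the contractile cytoskeleton, while MYH11, the smooth muscle myosin heavy chain, was at -0.07 (limma adjusted p = 0.598). Among 20 basal epithelial genes 9 were lower and 1 higher (median -0.14, camera adjusted p = 0.00103, and adjusted p = 0.286 with an estimated correlation). KRT5, a basal keratin, fell by 0.70 (SE 0.16, limma adjusted p = 0.00282), CSTA rose by 0.38 (SE 0.07, limma adjusted p = 0.000995), and TP63, the basal transcription factor, was at 0.04 (limma adjusted p = 0.727). Among 18 fibroblast genes 8 were lower and 0 higher (median -0.22, camera adjusted p = 0.00164, and adjusted p = 0.340 with an estimated correlation), among them PDGFRB at -0.49 and COL6A1 at -0.98. Adjusted over the list alone, 8 smooth muscle, 10 basal and 8 fibroblast genes were lower. Scores per library, relative to all genes, were lower in tumor for all 3 lists, with differences of -0.21 for smooth muscle (adjusted permutation p = 0.00394), -0.21 for basal epithelium (adjusted permutation p = 0.00052) and -0.16 for fibroblasts (adjusted permutation p = 0.043), and with 20, 20 and 14 of the tumors below the normal median. In the deeper libraries camera called the smooth muscle and basal lists and not the fibroblast list, whose median was -0.05 there (adjusted p = 0.0663).

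Developmental transcription factors and genes of the Wnt and TGF-beta pathways also carried less 5hmC. Of 36 developmental transcription factors measured, out of 84 fixed, 11 were lower and 0 higher (median -0.23, camera adjusted p = 3e-05, and adjusted p = 0.340 with an estimated correlation), including TBX4 (-0.72) and GATA4 (-0.27), and 15 were lower when adjusted over the list alone. Of 31 Wnt pathway genes 12 were lower and 2 higher (median -0.19, camera adjusted p = 0.000121, and adjusted p = 0.286 with an estimated correlation), including the ligand WNT4 (-0.63) and the secreted antagonist family member DKK3 (-0.49). Of 28 TGF-beta pathway genes 13 were lower and 2 higher (median -0.17, camera adjusted p = 0.000137, and adjusted p = 0.286 with an estimated correlation), including SMAD6 (-0.52) and LTBP2 (-0.38). Adjusted over the list alone, 15 Wnt and 15 TGF-beta genes were lower. Genes with promoters hypermethylated in prostate cancer had 8 lower and 1 higher of 28, with the same counts adjusted over the list alone (median -0.15, camera adjusted p = 0.00229, and adjusted p = 0.340 with an estimated correlation). HIC1, a transcriptional repressor, was at -1.54 and GPX3, a glutathione peroxidase, at -0.91. The mean normalized counts of HIC1 were 38.0 in tumor and 79.3 in normal tissue, a smaller change than that of its logs. Inflammation and interferon genes had 4 lower of 18 measured, out of 37 fixed (median -0.18, camera adjusted p = 0.0213, and adjusted p = 0.340 with an estimated correlation), including NFKB2 (-0.58) and the chemokine receptor CCR7 (-0.57). Hypoxia and glycolysis genes had 7 lower and 3 higher of 23 (median -0.16, camera adjusted p = 0.0475, and adjusted p = 0.340 with an estimated correlation), with the carbonic anhydrase CA12 at -0.27 and the prolyl hydroxylase EGLN3 higher, at 0.19. With the donor as a random block the hypoxia list was not called (adjusted p = 0.052), and with the density and length trends removed neither was it (adjusted p = 0.0921) nor inflammation (adjusted p = 0.0759). Adjusted over the list alone these were 4 lower, and 7 lower with 5 higher. By scores per library all 6 were lower, with adjusted permutation p from 0.00026 for Wnt to 0.0115 for inflammation and 15 to 19 of the tumors below the normal median. In the deeper libraries the developmental (median -0.08, adjusted p = 0.063) and inflammation lists (median -0.03, adjusted p = 0.197) were not called by camera, nor, without tumor 21 there, the hypermethylated (median -0.06, adjusted p = 0.131) and hypoxia lists (median -0.10, adjusted p = 0.118).

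More 5hmC was found over genes of DNA repair and cell division. Of 25 homologous recombination and repair genes 11 were higher and 2 lower (median 0.18, camera adjusted p = 0.0011, and adjusted p = 0.340 with an estimated correlation), including the checkpoint kinases ATR (0.28) and CHEK1 (0.24). Of 31 proliferation genes 9 were higher and 0 lower (median 0.08, camera adjusted p = 0.0195, and adjusted p = 0.340 with an estimated correlation), including the mitotic kinase AURKA (0.21) and DLGAP5 (0.29). Of 26 genes raised in prostate cancer RNA 8 were higher and 0 lower (median 0.09, camera adjusted p = 0.0304, and adjusted p = 0.440 with an estimated correlation), including GOLM1, EZH2 and FOLH1, which encodes prostate-specific membrane antigen (0.34, SE 0.11). Adjusted over the list alone, 12, 9 and 8 genes were higher. By scores per library the repair and proliferation lists were higher by 0.20 and 0.15 (adjusted permutation p = 0.00364 and 0.00208, with 5 and 4 tumors below the normal median), and the cancer RNA list did not pass (difference 0.10, adjusted permutation p = 0.112). In the deeper libraries camera called the repair list, with a median of 0.12, and the cancer RNA list, with 0.13, and not proliferation (median 0.10, adjusted p = 0.0663). Without tumor 21 there the repair list was not called either (median 0.11, adjusted p = 0.127).

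**Figure D2:**
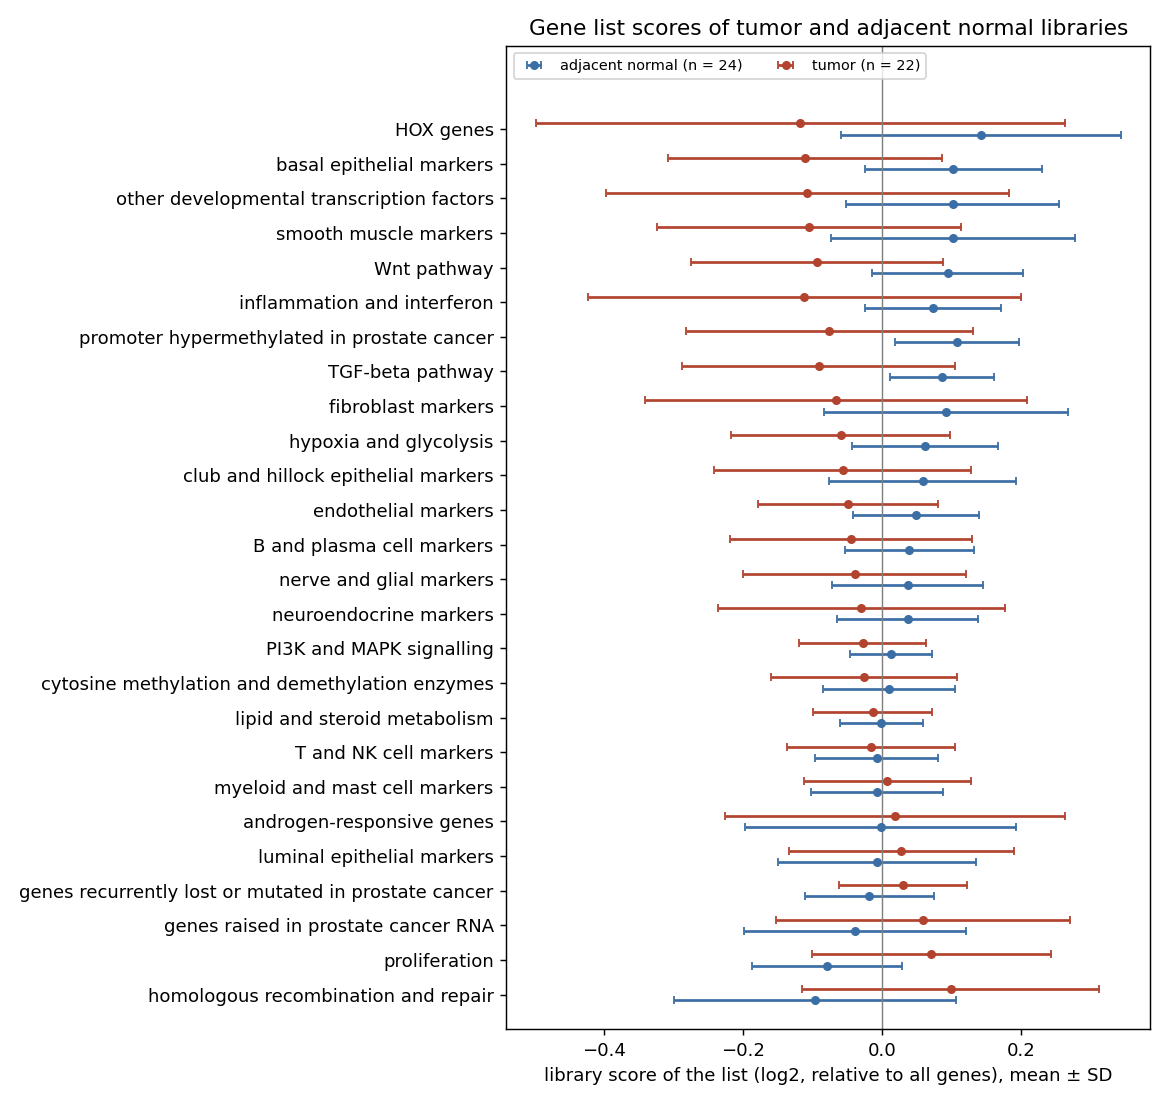
Score of each of the 26 gene lists per library (x axis, log2 units relative to all genes), as mean ± SD over 24 adjacent normal (blue) and 22 tumor (red) libraries. The difference in mean is -0.21 for smooth muscle and basal markers, 0.20 for repair genes and 0.02 for androgen-responsive genes.

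The other 14 lists were not called by camera. Androgen-responsive genes had a median of 0.07 with 2 genes higher and 1 lower of 22 (camera adjusted p = 0.608), with MAF at -0.45 and TPD52 higher, and were called only in the deeper libraries without tumor 21 (median 0.09, adjusted p = 0.0457). Luminal markers had a median of 0.04 with 2 higher and 1 lower of 19 (camera adjusted p = 0.608), with MSMB, a secreted luminal protein, higher (0.28) and GATA2 lower (-0.50). Endothelial markers had 5 lower of 15 (camera adjusted p = 0.189), with MMRN2 at -0.37 and EGFL7 at -1.06, and HOX genes 2 lower of 6 measured, out of 39 fixed (camera adjusted p = 0.0706), with HOXD10 at -0.69 and HOXA11 at -0.54. By scores per library the endothelial and HOX lists passed (both adjusted permutation p = 0.0115), as did club and hillock markers (adjusted permutation p = 0.0361), in which 0 genes of 9 passed and LCN2 was at -0.40 and PIGR at -0.14. Camera adjusted p was 0.801 for T and NK cells, 0.55 for B and plasma cells, 0.94 for myeloid and mast cells, 0.55 for nerve and glia and 0.247 for neuroendocrine markers. In these 5 lists 0 genes were higher and 1, 1, 1, 2 and 1 lower, among them IL2RB (-0.31), BLK, SIGLEC1 (-0.24), PMP22 (-0.31) and NCAM1 (-0.27). Of 17 cytosine methylation and demethylation enzymes 1 was higher and 2 lower, including DNMT3A (-0.23, camera adjusted p = 0.771 for the list). Of 35 genes recurrently lost or mutated 8 were higher, including KDM6A (0.23), and 3 lower (camera adjusted p = 0.608). PI3K and MAPK genes had 3 higher and 8 lower of 37, including FGFR1 (-0.36, camera adjusted p = 0.501 for the list), and lipid and steroid genes 3 higher and 3 lower of 31, including ACACA (0.23) and FDFT1 (-0.38, camera adjusted p = 0.803 for the list). Adjusted over the list alone, the counts were 0 lower for myeloid cells, 1 higher and 3 lower for nerve and glia, 9 higher for lost or mutated genes, 9 lower for PI3K and MAPK and 2 lower for lipid metabolism, and the same as over all genes for the other 9 uncalled lists. Medians and tests differed in sign for B and plasma cells, nerve and glia, and lipid metabolism, whose medians were 0.04, 0.03 and 0.02 while the test pointed down, and for androgen-responsive genes the mean was -0.04. CD8A, ITGAM, POU2AF1 and CHGA did not pass, at 0.15, 0.21, -0.19 and -0.34. Among the genes fixed in advance, KLK3 (0.10), FOXA1 (-0.22), ERG (0.12), TMPRSS2 (0.08), TET1 (0.18), TET2 (-0.01), TET3 (-0.02) and MYC (-0.14) did not pass.

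The second comparison asked whether the genes of a chromosome arm moved together. The short arm of chromosome 8, often lost in prostate cancer, carried less 5hmC: 104 of its 242 genes were lower and 0 higher, with a median of -0.16 and 83.9% of genes below 0. The odds of a gene being lower were 5.03 times those elsewhere (Fisher's exact test p = 6.16e-30, two-sided, genes not being independent). FGFR1, BLK, XKR5, GATA4 and FDFT1 lie there. The fall was uneven along the arm: next to the boundary with the long arm few genes passed as lower and many lay above 0. The score of 8p per library differed by -0.18 in tumor, and 21 of 22 tumors lay below the normal median (adjusted permutation p = 0.00041). On the long arm of chromosome 8, often gained, 100 of 420 genes were higher and 29 lower (median 0.07, camera adjusted p = 0.00753), TPD52, RAD54B and ESRP1 among them. Most of the 29 lower genes lay toward the far end of the long arm. The score of 8q per library did not pass (difference 0.08, adjusted permutation p = 0.168), while in the deeper libraries the median of 8q was 0.13 (camera adjusted p = 1.96e-10). Of the other arms fixed in advance camera called 16q (median -0.06, adjusted p = 0.000549). It did not call 17p (-0.03), 13q (-0.04), 6q (-0.03), 10q (-0.02), 5q, 18q, 7p or 7q (0.07), the medians of 5q and 18q being 0.005 and 0.003 and that of 7p 0.04. Camera also called Xp (0.11), Xq (0.12), 4q (0.08) and 3q (0.06) as higher and 22q (-0.06), 20q (-0.05) and 20p (-0.06) as lower. In the deeper libraries the calls of Xp (median 0.04, adjusted p = 0.154) and 20p (median -0.02, adjusted p = 0.225) ended, and 17p was called (median -0.09, adjusted p = 2.5e-08). The other arms called there and not in all libraries were 19p, 16p and 17q, lower, and 5p, 10p, 2q and 18p, higher. By scores per library the arms that passed were 8p, Xq (adjusted permutation p = 0.00471), Xp (adjusted permutation p = 0.0327) and 7q (adjusted permutation p = 0.0424). With an estimated correlation no arm passed (adjusted p = 0.322 for 8p), and random regroupings of the libraries often called as many arms as the 10 found, so the number of arms carries no weight of its own.

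**Figure D3:**
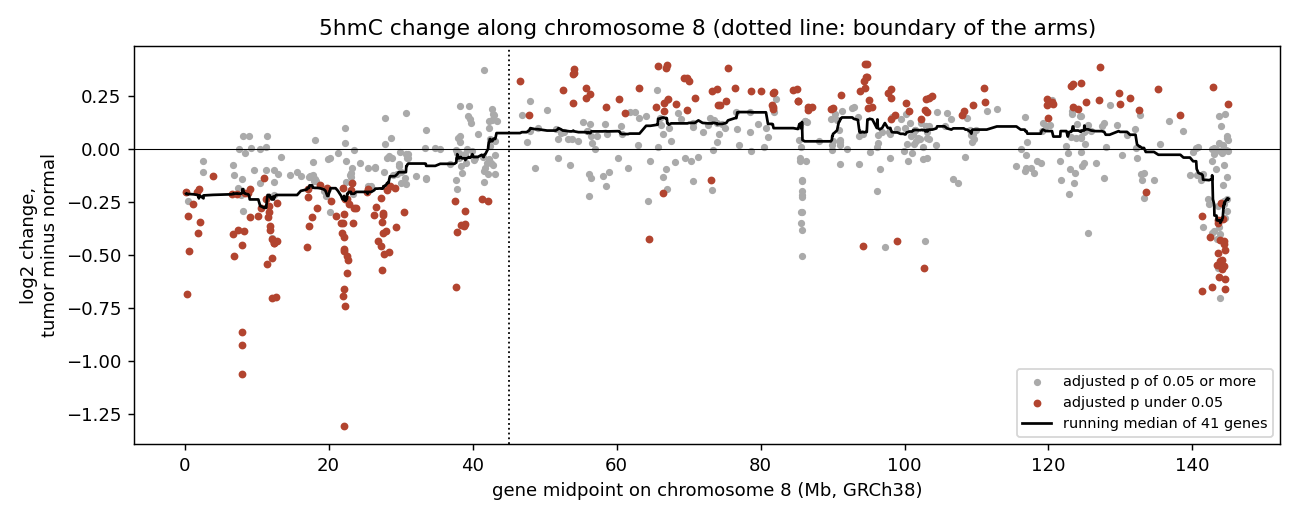
Log2 change (y axis, tumor minus normal) of each gene against its midpoint on chromosome 8 (x axis, Mb, GRCh38), with genes past the threshold in red, others in grey and a running median in black. On the short arm, left of the dotted line, 104 of 242 genes were lower, and on the long arm 100 of 420 were higher, while the running median falls below 0 near its end.

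**Figure D4:**
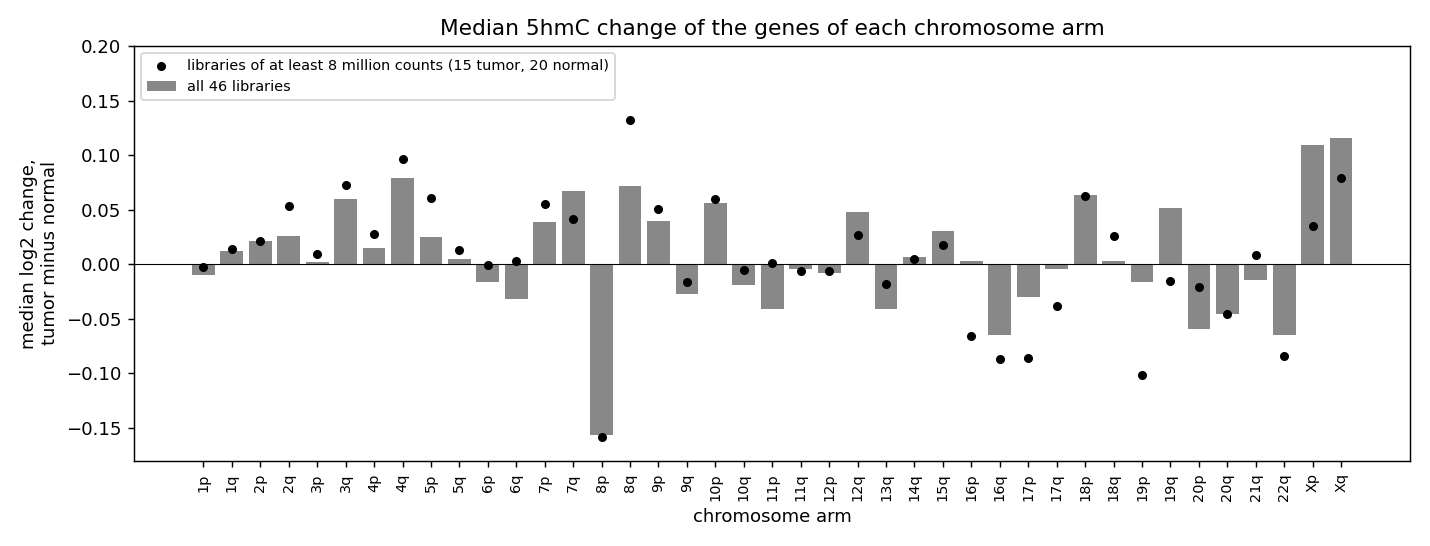
Median log2 change of the genes of each of 41 chromosome arms (y axis) in all 46 libraries (bars) and in the 15 tumors and 20 normals with at least 8 M counts (black points). The short arm of chromosome 8 is lowest at -0.16 in both sets.

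The third comparison asked whether tumors differ more among themselves than normal tissues do. Tumors lay farther from their group's centroid, at 0.71 ± 0.30 (SD, n = 22) log2 units per gene against 0.46 ± 0.25 (SD, n = 24), a difference of 0.25 (permutation p = 0.00215). It did not pass in name set A alone (0.19, permutation p = 0.158), with quantile normalization (0.10, permutation p = 0.0992) or in the deeper libraries (0.12, permutation p = 0.255). The first principal component held 39.6% of the variance and differed between tumor and normal (mean scores 14.4 ± 34.8 and -13.2 ± 22.2, permutation p = 0.00094). The 7 tumors under 8 M counts averaged 48.9 on it and the 15 deeper tumors -1.66, while the 4 normals under 8 M averaged -9.5 and the 20 deeper normals -14.0. The tumors overlapped, from 8.91 to 88.5 under 8 M and from -26.1 to 72.5 in the deeper ones, where tumor 21 (10.3 M) was highest, and without it the deeper tumors averaged -6.97.

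**Figure D5:**
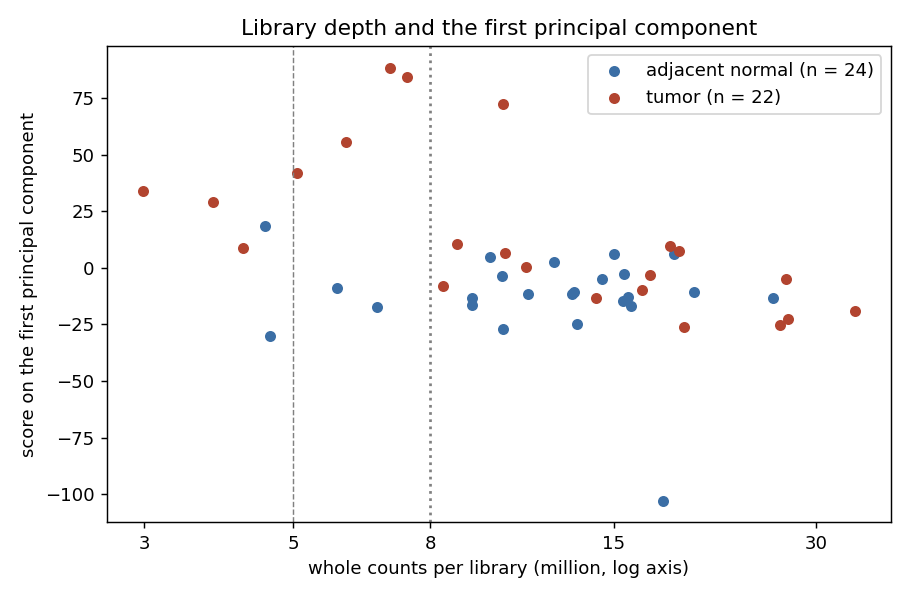
Score on the first principal component (y axis) against counts per library (x axis, M counts, log axis) for 22 tumors (red) and 24 adjacent normals (blue), with lines at 5 and 8 M. Tumors under 8 M average 48.9 and deeper tumors -1.66, with 1 deeper tumor at 72.5.

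Within name set A (12 tumors, 11 normals) 594 genes were higher and 1011 lower by limma. Within name set B (10 tumors, 13 normals) 0 genes passed and 3817 had an unadjusted p under 0.05. The difference in effect between the sets passed for 0 genes, with 1344 at an unadjusted p under 0.05, and for 2 lists by camera with the preset correlation and 0 with an estimated one. In the 5 donors with both tissues, with the donor as a block, 0 genes passed and 913 had an unadjusted p under 0.05.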

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

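The depth limits, leaving out a normal library or a deeper one, the trend removal, the covariate for spread about the length trend and the scores per library were chosen after the data were seen, and the other settings before. The 2334 higher and 2573 lower genes stayed within 1.5 times under both pseudocounts, both filters (a minimum of 10 removed 0 genes, so no filter gave identical counts), quantile normalization, median centring, the random donor block, the name set or depth covariate, array weights and the rank-sum test, with 1877 to 3031 higher and 2075 to 2948 lower. The name set covariate could change little, since the sets hardly differed over all libraries. Without adjacent normal library 10, chosen for standing apart on the first principal component, the higher and lower genes were 1786 and 2046. With the density and length trends removed they were 2852 and 2229, counted only over the 17635 genes with a position. Leaving out each library in turn gave 3476 (without tumor 19) to 6376 genes (without tumor 12), against 4907. They were 594 and 1011 in name set A, 0 and 0 by limma in name set B (3817 at an unadjusted p under 0.05), 1433 and 1664 without the libraries whose names hold R, 1446 and 1622 with at least 5 M counts, 0 and 0 with at least 8 M (4181 at an unadjusted p under 0.05), 0 and 0 there without tumor 21 (3544 at an unadjusted p under 0.05) and 1082 and 686 there without tumor 12, 1 and 1 there with the trends removed, and 1240 and 1238 with the spread covariate. With the replicate block on the 5 paired donors they were 0 and 0 (913 at an unadjusted p under 0.05), and 7 lists were called. The fits on part of the libraries have fewer of them, and beyond the tests of the limit of 8 M under the other observations the cause was not tested. In the libraries of at least 8 M counts, log2 changes correlated at 0.873 with those of all libraries across genes, which are not independent, and 100% of the called genes, picked on libraries that include these, kept their sign at a median 0.663 of their size. The random donor block ended the call of the hypoxia list (adjusted p = 0.052) and no other call of a list, arm or named gene, and 4899 of the 4907 genes were among the 5002 it called. Totals of like size could hold other genes. Of the 4907 genes 3641 were among the 4426 called with quantile normalization, and 3893 among the 5979 called with array weights. A test with edgeR had been planned for whole counts, and as an alternative if the normalized counts gave whole reads back. Whole numbers were recovered but may not be raw reads, and edgeR and DESeq2 were not run.

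The 12 lists called became 0 with the estimated correlation, 14 with scores per library and 6 in the deeper libraries without tumor 21. No called list changed direction in the test, although the median of the inflammation list was 0.0105 without tumor 21. Among 21 settings the Wnt, TGF-beta and smooth muscle lists kept their call in 20, the basal and hypermethylated promoter lists in 19, the fibroblast and developmental lists in 18, repair in 17, proliferation and cancer RNA in 16, inflammation in 12 and hypoxia in 9. The 10 arms called became 0 with the estimated correlation, 4 with scores per library and 16 with at least 8 M counts, with or without tumor 21, and 8p kept its call in 15 of 16 settings. The larger spread of tumors was 0.0975 with quantile normalization, 0.186 in name set A and 0.115 with at least 8 M counts, none past the threshold, and the cause was not tested. Of 64 named genes past the threshold 0 changed direction, and their calls held in 853 of the 1210 combinations of gene and setting.

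Directions turned, relative to other genes, for lists that were not called. Scores per library put T and NK cells at -0.0075. Quantile normalization put genes recurrently lost or mutated at -0.0261, and median centring put myeloid cells at -0.00659. The paired donors put androgen-responsive genes at -0.0209, endothelial markers at -0.0137, methylation enzymes at -0.024 and genes recurrently lost or mutated at -0.0266. Name set B put T and NK cells at -0.0131, myeloid cells at -0.0206, methylation enzymes at 0.0126 and lipid metabolism at 0.0358. Myeloid cells were at 0.00443 without the R libraries and at 0.000668 without adjacent normal library 10. B and plasma cells were at 0.0781 with array weights and 0.0712 with at least 8 M counts, where genes recurrently lost or mutated were at 0.00948 and lipid metabolism at 0.00701. Without tumor 21 there, B and plasma cells were at 0.08799, neuroendocrine markers at -0.0117, genes recurrently lost or mutated at 0.0186, lipid metabolism at 0.0241 and 18q at 0.0389. Trend removal put genes recurrently lost or mutated at -0.0311, and in the deeper libraries it put club markers at 0.04999, B cells at 0.0677, genes recurrently lost or mutated at -0.0202 and lipid metabolism at 0.0124. Among arms, 13q turned in name set A (0.0199), the called arm 22q (0.0201) and 7p (0.0148) in name set B, and 18q with at least 8 M counts (0.0263) and with the spread covariate (0.0301).

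Among genes that did not pass, the paired donors turned TP63 (-0.114), TET3 (0.0702), MYH11 (0.0739) and CHGA (0.0809). Quantile normalization turned FOXA1 (0.111) and MYC (0.0109), and array weights FOXA1 (0.0142) and TET2 (0.0796). Name set A turned TMPRSS2 (-0.114), TET2 (0.058) and TET3 (0.0545), and name set B TP63 (-0.0846). At least 8 M counts turned PIGR (0.0158), FOXA1 (0.0366), TET2 (0.0805) and TET3 (0.0414), without tumor 21 also PIGR (0.0345), FOXA1 (0.103), TET2 (0.0978), TET3 (0.0514) and MYC (0.0282), and with tumor 21 kept and the trends removed PIGR (0.0765), FOXA1 (0.0698), TET2 (0.0273), TET3 (0.0878), TP63 (-0.00525) and MYC (0.0114). TET2 was at 0.00329 with the depth covariate, 0.00383 with at least 5 M counts, 0.00503 without adjacent normal library 10 and 0.0644 with the spread covariate, and TET3 at 0.00836 with the trends removed and 0.0053 with the spread covariate. The cause of these turns was not tested.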

Other observations

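Of 22 gene families, chosen after the data were seen, camera called 6. Keratin genes carried less 5hmC in tumor, with 17 of 35 lower and 1 higher and a median log2 change of -0.27 (camera adjusted p = 2.17e-05, and adjusted p = 0.492 with an estimated correlation). Semaphorins and plexins, guidance cues and their receptors, had 10 of 31 lower and 1 higher (median -0.19, camera adjusted p = 0.0003), and collagens 17 of 43 lower and 3 higher (median -0.14, camera adjusted p = 0.0115). ZNF zinc finger genes had 98 of 458 higher and 35 lower (median 0.10, camera adjusted p = 0.00349). Potassium channels had 19 of 71 lower and 3 higher (median -0.11, camera adjusted p = 0.00349), and olfactory receptors 4 of 20 higher (median 0.14, camera adjusted p = 0.0333). Families were set by symbol, so the olfactory receptors take in an antisense RNA gene, which is among the 4 higher. With an estimated correlation the adjusted p was 0.492 for each of these families too. These 6 medians kept their sign under quantile normalization and median centring, although that of keratins was -0.15 with quantile normalization, -0.14 with the trends removed and -0.10 in the deeper libraries. In the deeper libraries camera called keratins, semaphorins and plexins, and olfactory receptors (each adjusted p = 0.0044), and not collagens or potassium channels (both adjusted p = 0.331) or ZNF genes (adjusted p = 0.0752). The medians there were -0.11 for semaphorins and plexins, -0.02 for potassium channels and 0.05 for ZNF genes. Camera also called there UDP-glucuronosyltransferases (median 0.17, adjusted p = 0.0044), long intergenic noncoding RNAs (median 0.07, adjusted p = 0.00863) and, as lower, ribosomal proteins (median -0.08, adjusted p = 0.00561), whose median in all libraries was -0.04 and turned to 0.0021 with quantile normalization and 0.08 with the trends removed.

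Of the tests below, those on trends, on normals of low depth, on single deeper libraries left out, on arms in the deeper libraries and on the name sets were chosen after their result or the data were seen. So were the scores per library and the covariate for spread about the length trend. The splits, the random removals and the spread of 8p over tumors had a prediction written before their result was computed, though after other looks at the data. The comparisons of arms often lost or gained had none. Chance regrouping is argued against for the genes. Of 100 splits of the 46 libraries only 1, the real one, gave 2334 higher or 2573 lower genes. The highest of the others was 0 in each direction. With 100 splits the share cannot be put below 1 in 100, and the splits take no account of an adjustment of the values before deposit, raised below. For the number of lists chance regrouping stays open, since 6 of 100 splits called at least the 12 found and the highest other was 14. For the number of arms it stays open too, since 68 of 100 called at least 10 and the highest other was 22. Splits that call so many arms point to a structure of the libraries, which was not tested further.

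The first pattern is that 0 genes passed by limma in the libraries of at least 8 M counts (4181 at an unadjusted p under 0.05), and it rests on few libraries, since 1768 passed there without tumor 12, 72 without tumor 11 and 1 without adjacent normal 7 or 14. Whether having fewer libraries accounts for it stays open. Only 1 of 100 random removals of 7 tumors and 4 normals gave as few calls (median 2619, 5th percentile 124). So small a share had been set beforehand to count against this explanation. It was left open after the data were seen, since the 1768 without tumor 12 lie within the calls of the removals. Leaving out any other deeper library gave at most 72, below that 5th percentile. The limit was also picked after the shallow tumors were seen to stand apart. Low depth in itself stays open too, since an exact permutation test did not exclude that the 4 normals of low depth, which scored 4.48 above the 20 deeper ones on the first component, were shifted by 25.3 against a gap of 50.6 in tumors (p = 0.0956, two-sided), although without adjacent normal 10 it did (p = 0.00226). Trends over gene density and length as the whole cause are argued against, since with them removed 5081 of the 17635 genes with a position passed in all libraries, and 2 in the deeper ones. Of the 5081 genes 3403 were among the 4907, which were called over all 20396 genes. With a library's spread about its length trend as a covariate in all libraries 1240 genes were higher and 1238 lower. That spread was computed from the same values as the comparison and was not fitted in the deeper libraries, so it decides nothing here. A difference in tissue or in the state of the fixed DNA between tumors of low and high depth stays open, untested.

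The second pattern is the lower 5hmC of 8p and the higher 5hmC of 8q, and for 8p neither the trends nor the shallow libraries account for the whole of it, since trend removal left its median at -0.19 relative to all genes and the deeper libraries had -0.17. Loss and gain of DNA copies in tumors is a candidate explanation, and it cannot be told apart from a change in 5hmC without input libraries. The spread of 8p over tumors relative to normals ranked 5 of 41 arms, where a rank of 4 or higher had been asked for. That of 8q ranked 21, the middle of the arms, with an SD of 0.167 over tumors and 0.0975 over normals. Such a rank depends on the spread over normals too, and a change of copies shared by most tumors need not widen the spread. The ranks therefore decide nothing on a loss or a gain. The 8 arms often lost differed from the 30 other arms by -0.06 on average (permutation over arms, adjusted p = 0.0149), without 8p by -0.04 (adjusted p = 0.0453), with the trends removed by -0.08 (adjusted p = 0.00032), in the deeper libraries by -0.05 (adjusted p = 0.0453), and there without 8p by -0.03 (adjusted p = 0.133). The 3 arms often gained differed by 0.04 (adjusted p = 0.133), with the trends removed by 0.03 (adjusted p = 0.178) and in the deeper libraries by 0.07 (adjusted p = 0.0453). These p-values treat arms as independent, which may not hold, since 68 of 100 splits of the libraries called at least 10 arms, and by scores per library only 8p of the arms often lost passed (adjusted permutation p from 0.083 to 0.792 for the others) and only 7q of those often gained (adjusted permutation p = 0.0424, against 0.168 for 8q and 0.216 for 7p).

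The third pattern is that, over all libraries, name sets A and B differed less than random splits of the libraries did. Over all genes the mean squared t between the sets was 0.145, against 0.374 to 2.4 in 99 random splits. Only 1 of 100, the real one, was as small, which argues against chance. Between the sets 0 genes had an unadjusted p under 0.05. Within a tissue the sets were less alike, with a mean squared t of 0.617 in tumors alone and 0.826 in normals alone. These values were not compared with random splits within a tissue. Adjustment of the values between the sets before deposit may explain the small difference over all libraries, and this explanation remains open. The differences between the sets in tumors and in normals opposed each other across genes (Pearson correlation -0.772, genes not being independent). With tumors and normals spread almost evenly over the sets, a small difference over all libraries forces such an opposition. The correlation therefore decides nothing. If there was such a step, the whole numbers behind the table are not raw reads, and p-values that take no account of it may be too small. With the name set as a covariate 2213 genes were higher and 2457 lower. With so small a difference between the sets over all libraries the covariate could change little, so these counts do not bear on such a step. No biological explanation was tested.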
